A study of Helianthus annuus with 9 samples.

How the data were processed

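Seeds of the sunflower line L-1-OL-1, a line with a high oleic acid content, were collected at day 7, day 22 and day 37, with 3 libraries per day and 9 in all. The labels do not state the event from which the days were counted. Total RNA was depleted of ribosomal RNA and sequenced on the BGI500 platform, per the labels' protocols. The labels do not say whether the 3 libraries of a day came from separate plants, so p-values measure the spread between these libraries.

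HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5 were used upstream, per the submitters' processing notes, which give no role for any of them. Gene levels for mRNA and for lncRNA were deposited as FPKM (fragments per kilobase of transcript, scaled to the library's total), per the file headers, and the total used for their scaling was not stated. No read counts were used here, so the depth of each library is unknown. Junction levels of 3482 circular RNA (circRNA) were deposited as a scaled signal with no unit in the file headers. Within each library this signal took the value 0 or multiples of a step between 9.47 and 14.5, to within 0.75 for all values below 400, and the lowest value above 0 was 19. Other deposited values were the exon starts and ends of 40778 assembled transcripts in 38992 loci, whose second column names Cufflinks.

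The mRNA table and the lncRNA table each held 65535 features, which with the header line fills the row limit of the old spreadsheet format, so each may be a part of a longer table. The assembly file ends at the same number of lines and covers 7 sequences, of which 5 hold most of its exons. Numeric gene IDs were carried by 52513 mRNA features, and 47455 of these matched the gene table of assembly HanXRQr2.0-SUNRISE, 46947 as protein-coding genes. Another 13022 were assembled loci (MXLOC names). Of the lncRNA features 7573 carried numeric IDs, of which 5677 matched, and 57962 were assembled loci (LXLOC names). Matched genes are given by their symbol, LOC followed by the ID. The sequences named in the files carry other versions than that assembly, so its coordinates were not used, only its symbols, gene classes and gene order. The genome build of the files is not given in the sources used here. Positions are as the files give them. On the 5 sequences of the assembly file, 1091 circRNA were listed, of which 47 started at an assembled exon start and 124 started 1 base before one, so part of the circRNA starts may count from 0.

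Neither the files nor the gene table pair IDs with product names. Gene lists fixed before the data were examined, on oil bodies, storage proteins, fatty acid synthesis and other seed processes, were matched on product names and could not be used. The tests, the comparisons, the rule for named genes and the alternatives not said to be added were fixed at the same point. The rule took, in each comparison, the 5 risen and 5 fallen mRNA genes with the largest absolute log2 fold change among those called and with replicate values that did not overlap between days. Its condition on product names could not be applied. It also took the 3 risen and 3 fallen lncRNA and the 2 risen and 2 fallen circRNA with the largest change, the 3 circRNA with the highest mean, and the 5 mRNA genes with the highest mean FPKM on each day.

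Values were analysed as log2(FPKM + 1) for features with at least 1 FPKM in at least 3 of the 9 libraries, in 1 fit of all 9 libraries per table, with limma 3.58.1 in R 4.3.3 (trended and robust empirical Bayes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The circRNA signal was treated in the same way as log2(signal + 19), for circRNA above 0 in at least 3 libraries. All adjusted p-values given for genes, lncRNA and circRNA come from these limma fits. The fits share the estimate of spread over the features of a table, so a p-value does not rest on the feature's own spread alone. Very small p-values of the lncRNA table cannot be set against those of the mRNA table. Numbers per library were compared by exact two-sided permutation tests of 3 against 3 libraries, whose smallest possible p is 0.1. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

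The fits were tested on simulated data with 100 changed genes per size. At a log2 change of 1.5, 67% of mRNA genes were recovered for day 22 against day 7 and 64% for day 37 against day 22. At a log2 change of 3, 96% were recovered in both. For lncRNA the recovered shares at a log2 change of 1.5 were 80% and 84%, and for circRNA 55% and 50%. The simulated noise was drawn for each feature on its own, and the changes were set on day 22 alone. It thus held no deviations shared across features within a library and no change of most features. The recovered shares do not show how the fits behave where these are present, as they are here.

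The labels number the libraries of each day from 1 to 3 without saying that equal numbers share a plant or a batch. For mRNA, the correlation across genes of the deviations from the day means, between day 37 and day 22 libraries of equal number, was 0.77, 0.15 and 0.78. Each was above 0.1, so the numbers were taken to pair the libraries of these 2 days. The same libraries gave 0.52, 0.09 and 0.55 for lncRNA, and 0.17, 0.06 and 0.24 for circRNA. The source of the pairing is this check alone, and for mRNA the day 37 library numbered 2 correlated more with the day 22 library numbered 1 (0.53) than with its own number. A fit with the replicate number as a block was run as an alternative for each comparison. Further alternatives changed the pseudocount, the filter on low values, the scaling and the threshold, and left out each library in turn. Added after the data were seen were a scaling on the 453 mRNA genes with at least 10 FPKM in all 9 libraries, fits of annotated genes alone, a filter at 10 FPKM, fits without both late libraries numbered 3, the classes of both steps without each library in turn, and fits without the genes that were higher in replicate 3 than in replicate 1 on both late days.

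Whether the quantification used strand is not stated. Of 252 assembled loci antisense to a gene with at least 10 FPKM on day 7, 98.8% were below 5% of that gene's FPKM. Levels of overlapping genes, and of near-identical gene copies that could share reads, are uncertain, since how such reads were divided is not given in the sources used here.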

Results

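RNA was sequenced from developing seeds of 1 sunflower line at day 7, day 22 and day 37, to follow mRNA, long non-coding RNA (lncRNA) and circRNA over seed development. Each day had 3 libraries. The depth of the libraries is unknown, since the tables give FPKM and scaled signals, not counts. The FPKM of the mRNA table summed to 545700 ± 3477 on day 7 (SD, n = 3), 282000 ± 51500 on day 22 and 222100 ± 65390 on day 37. In single libraries the sum ran from 542177 to 549131 on day 7, from 228550 to 331317 on day 22 and from 149870 to 277263 on day 37. The lowest sum of both late days was in the library numbered 3. The mRNA table listed 20900 ± 62.9 features at 1 FPKM or more on day 7, 29560 ± 2026 on day 22 and 27540 ± 1736 on day 37 (SD, n = 3). The lncRNA table listed 3222 ± 36.6, 27420 ± 10350 and 37440 ± 8301. In single late libraries this number lay between 17642 and 46878, and its highest value on each late day was again in the library numbered 3.

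The first comparison asked which mRNA changed between day 7 and day 22. The most strongly fallen genes were among the most abundant of day 7. LOC110865032 went from 8105 ± 166 FPKM to 2.05 ± 1.11 (SD, n = 3) and so fell by 11.43 ± 0.42 (SE) on the log2(FPKM + 1) scale, with a limma adjusted p of 4.48e-10. LOC110897318 fell from 5320 ± 250 to 1.07 FPKM and LOC110868684 from 6538 ± 553 to 1.97 FPKM. LOC110865284 fell from 3821 ± 44.7 to 1.21 FPKM, and LOC110897316 from 4148 ± 212 to 1.47 FPKM. Among the genes that rose, LOC110917110 went from 0.0167 FPKM to 477 ± 216 (log2 fold change 8.76 ± 0.67, adjusted p 1.83e-07) and LOC110927644 from 2.36 FPKM to 1426 ± 630. The assembled locus MXLOC_140769 was listed at 0 in all 3 day 7 libraries and at 362 ± 71.3 FPKM on day 22. LOC110936707 rose from 0.0267 to 359 ± 146 FPKM, and LOC110911836 from 0.0967 to 367 ± 95.8 FPKM.

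Of the 36401 mRNA features tested, 12407 rose and 9074 fell. Annotated genes made up 8565 of the fallen and 5647 of the risen features, and assembled loci the other 509 and 6760. Of the risen assembled loci, 94.8% were higher in replicate 3 than in replicate 1 on both late days, and of the risen annotated genes 65.8%. The same held for 5.4% of the fallen annotated genes. The median log2 change of all tested features was 0.09 as deposited, 0.02 after quantile normalization, 0.32 with trimmed mean scaling, 0.56 with median-of-ratios scaling and 0.82 after scaling on 453 genes with at least 10 FPKM in every library. The share of risen features among those called was 57.8%, against 47.1% with quantile normalization and 78.0% with the scaling on 453 genes. With quantile normalization the count of calls was 12423, and among annotated genes alone it was 14060. Features that fell outnumbered those that rose with a filter at 5 FPKM, where 3266 rose and 6870 fell (32.2% risen). Among the annotated genes 40.1% of the calls were rises.

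**Figure D1:**
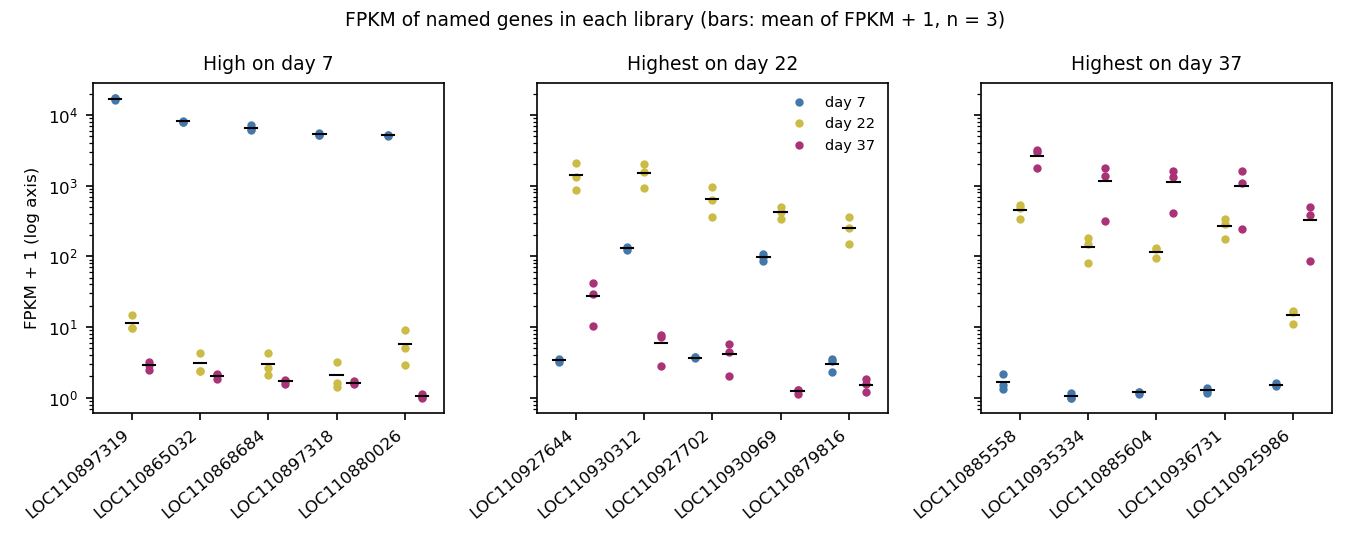
FPKM + 1 of 15 named mRNA genes in each library is shown on a log axis, with 1 point per library coloured by day and black bars for the mean of each day (n = 3). LOC110865032 lay near 8105 FPKM on day 7 and 1.03 FPKM on day 37, whereas LOC110885558 rose from 0.663 to 2628 FPKM.

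The comparison of day 37 with day 22 covered the later step of the time course. Some genes that had been abundant on day 22 were nearly gone on day 37. Others of the 5 most abundant on day 22 were not called at this step. LOC110932526 stood at 3351 and then 1853 FPKM, the gene with ID 110886340 at 1824 and 594 FPKM, and LOC110877981 at 1763 and 904 FPKM. LOC110930312 went from 1495 ± 549 to 4.87 ± 2.67 FPKM (SD, n = 3) and so fell by 8.05 ± 0.56 (SE) on the log2 scale, with a limma adjusted p of 5.42e-07. LOC110930969 fell from 418 ± 84.2 to 0.233 ± 0.0987 FPKM (log2 fold change −8.39), and LOC110927702 from 651 ± 305 to 3.09 FPKM. LOC110879816 fell from 254 ± 108 to 0.53 FPKM and LOC110872272 from 154 ± 42.7 to 0.16 FPKM. LOC110927644, among the most strongly risen at day 22, fell back from 1426 ± 630 to 26.1 ± 15.6 FPKM. The 5 most strongly risen genes reached between 26.5 and 324 FPKM. LOC110925986 rose from 13.8 ± 3.33 to 324 ± 215 FPKM (log2 fold change 4.14 ± 0.57, adjusted p 1.01e-04), and LOC110883894 from 6.8 to 125 ± 36.9 FPKM. LOC110889963 rose from 1.18 to 57.4 ± 32.4 FPKM and LOC110895100 from 0.663 to 26.5 ± 11.2 FPKM. MXLOC_215847 was listed at 0 in all 3 day 22 libraries and at 26.7 ± 10.9 FPKM on day 37. LOC110885558 also rose at this step, from 448 ± 99.4 to 2628 ± 769 FPKM (SD, n = 3), and LOC110935334 from 134 to 1146 ± 750 FPKM.

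Of the tested mRNA features, 307 rose and 6054 fell at this step. The risen count rested on day 37 replicate 3: without this library 1321 rose and 5069 fell, a risen share of 20.7%, and without both late libraries numbered 3, 953 rose and 6189 fell. Without day 37 replicate 2, 185 rose. Among the fallen features, 83.7% were lower in replicate 3 than in replicate 1 on both days, and among the risen 76.5%. The risen share of the calls was 4.8% as deposited, but 29.3% with median-of-ratios scaling, 22.2% with trimmed mean scaling and 27.6% with quantile normalization. The median log2 change moved from 0.01 to 0.50, 0.37 and 0.27 with these 3 scalings. Against that shift, the 5 fallen and 5 risen genes named above kept their direction and their call under each scaling.

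Day 37 was also compared with day 7, to give the net change over the time course. LOC110897319, the most abundant mRNA of day 7 at 16830 ± 736 FPKM (SD, n = 3), stood at 10.3 ± 2.88 FPKM on day 22 and 1.86 ± 0.394 FPKM on day 37. It fell by 12.53 ± 0.46 (SE) on the log2 scale, the largest fall of the tested mRNA features in this comparison (limma adjusted p 3.68e-10). LOC110880026 fell from 5128 ± 134 to 0.0467 FPKM. LOC110865032, LOC110868684 and LOC110897318 were again among the 5 most strongly fallen. LOC110885558 rose from 0.663 FPKM through 448 ± 99.4 on day 22 to 2628 ± 769 on day 37 (log2 fold change 10.61 ± 0.52, adjusted p 2.48e-09). LOC110935334 reached 1146 ± 750 FPKM from 0.06, LOC110885604 1107 ± 619 FPKM from 0.183, LOC110936731 982 ± 693 FPKM from 0.263 and LOC110897821 844 ± 580 FPKM from 0.15.

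In this comparison 14346 mRNA features rose and 14123 fell. Of the risen features 87.7% were higher in replicate 3 than in replicate 1 on both late days, and of the fallen 3.8%. The risen share was 50.4% as deposited, 66.4% with median-of-ratios scaling and 61.6% with the scaling on 453 genes, and the median log2 change was −0.32, 0.67 and 0.35. With a filter at 5 FPKM 2883 rose and 10258 fell, and among annotated genes alone 6391 rose and 13236 fell.

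Not all abundant genes changed past the threshold. LOC110932526 stood at 5395 ± 266 FPKM on day 7, 3351 ± 941 on day 22 and 1853 ± 1168 on day 37 (SD, n = 3). Its log2 change at day 22 was −0.73 ± 0.84 (SE) with a limma adjusted p of 0.432, and the sign of this change turned with quantile normalization and with the scaling on 453 genes. LOC110877981 stood at 3570, 1763 and 904 FPKM, and the assembled locus MXLOC_215740 at 1922, 990 and 1769 FPKM. The gene with ID 110886340, which has no match in the gene table, stood at 3044, 1824 and 594 FPKM. None of these 3 was called in a single step, while LOC110877981 (log2 fold change −2.25, adjusted p 0.0166) and the gene with ID 110886340 (ID110886340, −2.67, adjusted p 0.00697) fell from day 7 to day 37. MXLOC_034693, a locus of 6 exons on NC_035435.1 from 159573932 to 159686674 that overlaps LOC110930788 and LOC110930790, fell from 10180 ± 286 FPKM on day 7 to 69.8 ± 24.2 and then to 16.3 ± 10.0. The call of its later log2 change of −2.22 was lost with no filter and without day 22 replicate 1 or 2. LOC110895162 rose from 4.68 to 316 ± 139 FPKM on day 22 and stood at 1151 ± 747 on day 37. Its later log2 change of 1.64 had an adjusted p of 0.0858 and was called with the replicate number as a block.

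The order of changes over both steps was then described for each mRNA feature. LOC110927644 and LOC110930312 were among the 1022 features that rose at day 22 and fell at day 37. LOC110885558 was among the 108 that rose at both steps, and LOC110897319 among the 2155 that fell at both. Another 11277 rose at day 22 with no later call, 6890 fell with no later call, and 29 fell and then rose. If the calls of both steps were independent, 2064 would rise and fall, 105 rise at both, 1509 fall at both and 76.5 fall and rise. Simulated unchanged groups that share the day 22 libraries gave 0 in each of these classes. All 36401 simulated features stayed uncalled at both steps, so each class had to be 0. The simulation held no changed features, so it cannot show how noise shared through the day 22 libraries affects the classes. The observed class sizes depended on the settings. The risen-then-fallen class held 1026 features with median-of-ratios scaling, 1311 with a pseudocount of 0.1 and 1855 with the scaling on 453 genes, and 824 to 1200 when single libraries were left out. The class that rose at both steps held 446, 323 and 162 with these 3 settings, and 258 without day 37 replicate 3. The class that fell at both held 1025, 3330 and 1025, and 1574 to 3018 when single libraries were left out. The class that fell and then rose held 244, 105 and 25, but 426 without day 37 replicate 3 and 193 without both late libraries numbered 3. The numbers given for independent steps, such as 76.5, hold for the main fit alone. They were not computed for the other settings, so these counts cannot be set against them.

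**Figure D2:**
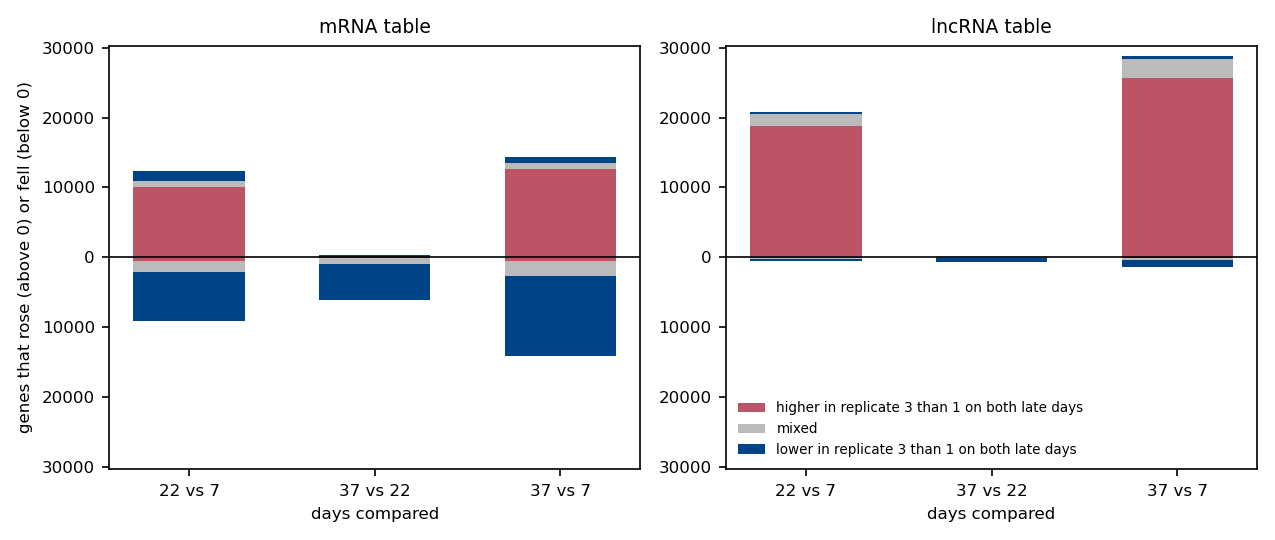
Bars give the number of mRNA features (left) and lncRNA features (right) that rose, drawn above 0, or fell, drawn below 0, in each pair of days, coloured by whether replicate 3 was higher or lower than replicate 1 on both late days. Of the lncRNA features risen at day 22, 90.4% were higher in replicate 3.

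For lncRNA the same comparisons asked how non-coding transcripts changed. LXLOC_204293 fell from 610 ± 116 FPKM on day 7 to 0.157 on day 22 and 0.1 on day 37 (SD, n = 3). The log2 change at day 22 was −9.04 ± 0.28 (SE), with a limma adjusted p of 2.91e-23. LXLOC_160427 fell from 274 ± 6.6 to 0.103 FPKM on day 22. LXLOC_026551, an intergenic locus of 2 exons on NC_035435.1 from 104524964 to 104635760, fell from 325 ± 25.4 to 0.0667 FPKM. LXLOC_125840 fell from 287 ± 21.2 FPKM on day 7 to 0.08 FPKM on day 37. LXLOC_216026 rose from 0.16 FPKM to 1213 ± 388 on day 22 and 1772 ± 452 on day 37, and LXLOC_137664 from 0.13 FPKM to 1069 ± 318 and 1475 ± 319. LXLOC_215589 rose from 0.0733 FPKM to 757 ± 298 on day 22, and LXLOC_215785 from 0.393 FPKM to 1406 on day 37. These 4 risen loci were higher in replicate 3 than in replicate 1 on both late days. LXLOC_216026 stood at 847 and 1620 FPKM in replicates 1 and 3 of day 22, and at 1384 and 2269 on day 37. The median of single-exon intergenic loci moved alike in these libraries, from 0.62 to 1.22 and from 1.03 to 1.59 FPKM. Whether that low signal stems from DNA or RNA is left open below, and so is the source of these rises.

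Between day 22 and day 37, LXLOC_128291 fell from 577 ± 288 to 14.4 ± 10.3 FPKM (SD, n = 3), with a log2 change of −5.37 ± 0.45 (SE) and a limma adjusted p of 1.62e-10. The annotated lncRNA LOC110878354 fell from 115 to 2.44 FPKM, and LXLOC_031170, a single-exon intergenic locus on NC_035435.1 from 66433810 to 66435227, from 54.6 to 0.69 FPKM. LXLOC_215995 was listed at 0 on day 7 and day 22 and at 56.7 ± 22.5 FPKM on day 37. LXLOC_162691 rose from 0.0667 to 30.5 ± 17.3 FPKM. LXLOC_017534, a single-exon intergenic locus on NC_035434.1 from 179339324 to 179341936, rose from 2.46 to 28.6 ± 7.37 FPKM.

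Of 34147 lncRNA features tested, 20811 rose and 578 fell at day 22, 176 rose and 637 fell from day 22 to day 37, and 28807 rose and 1326 fell from day 7 to day 37. The filter admitted a feature through any 3 libraries. Only 3187 to 3260 lncRNA features per day 7 library were at 1 FPKM or more, so most tested features passed through the late libraries. The excess of rises against day 7 is thus partly set by the filter. Of the features risen at day 22, 90.4% were higher in replicate 3 than in replicate 1 on both late days, and 20569 of them were assembled loci. The median log2 change at day 22 was 1.11 as deposited, 0.99 with median-of-ratios scaling, 0.86 with trimmed mean scaling and −0.02 with quantile normalization. The risen share of the calls at day 22 was 97.3%, against 66.4%, 53.8% and 46.9% with these 3 scalings. For day 37 against day 7 it was 95.6%, against 70.2%, 52.9% and 47.5%. For day 37 against day 22 it was 21.6%, against 10.6% with the scaling on 453 mRNA genes, 32.0% (232 risen) without day 37 replicate 3 and 31.8% (390 risen) without day 22 replicate 3. Among annotated lncRNA alone, 241 rose and 179 fell at day 22, 20 rose and 261 fell from day 22 to day 37, and 319 rose and 571 fell from day 7 to day 37.

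The share of tested features that was called was 62.6% for lncRNA and 59.0% for mRNA at day 22, 2.4% and 17.5% from day 22 to day 37, and 88.2% and 78.2% from day 7 to day 37. Within the features of equal mean level the order at day 22 varied. It was 85.9% for lncRNA and 66.5% for mRNA at a mean log2(FPKM + 1) of 1 to 2, and 34.0% and 48.3% at 6 or more. Genes are not replicates, so these shares were not tested. The lncRNA shares against day 7 also rest on the filter, which admitted most lncRNA features through the late libraries.

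CircRNA were compared by the number above 0 per library and by the level of each. On day 7 the 3 libraries held 1154 ± 72.2 circRNA above 0 (SD, n = 3), on day 22 433 ± 137 and on day 37 476 ± 250. The exact two-sided permutation test gave p = 0.1 for day 22 against day 7, p = 0.1 for day 37 against day 7 and p = 0.9 for day 37 against day 22 (n = 3 each), where 0.1 is the smallest p possible. With the lower quartile of the values above 0 as the minimum, the mean numbers were 1153.7, 231.7 and 266.3. That minimum was 28. The lowest value above 0 was 28 or 29 in the day 7 libraries and 19 to 21 in the late ones. The minimum could thus lower only the late numbers and is no check on the difference. Among circRNA above 0 in at least 2 libraries of a day, 522 were seen on day 7 alone, 63 on day 22 alone, 93 on day 37 alone and 81 on all 3 days. The numbers in the late libraries were 585, 396 and 319 on day 22 and 697, 526 and 205 on day 37.

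**Figure D3:**
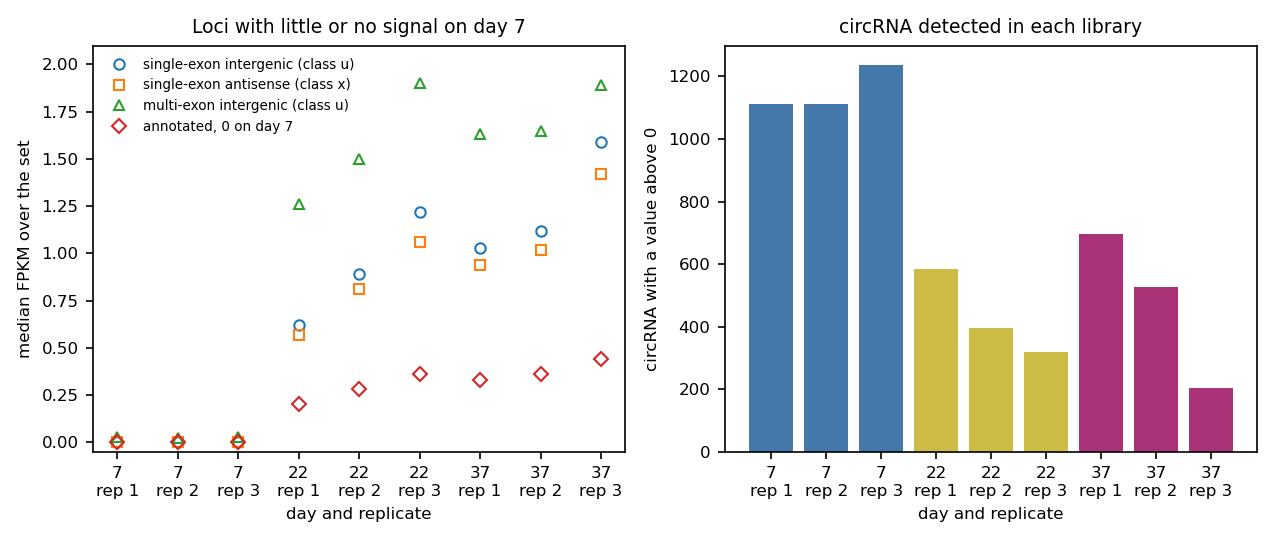
For each of the 9 libraries, the left panel gives the median FPKM of assembled loci of 3 classes and of annotated genes at 0 in all day 7 libraries, and the right panel the number of circRNA above 0, coloured by day. Medians of the single-exon intergenic loci are 0 on day 7 and 0.62 to 1.59 FPKM in the late libraries, while circRNA numbers are 1111 or more on day 7 and 697 or fewer later.

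The circRNA with the highest day 7 signal among those named, on NC_035433.1 from 75074236 to 75089399, stood at 47020 ± 2163 on day 7 (SD, n = 3) and was listed at 0 in all 6 late libraries (limma adjusted p 2.53e-08 at day 22). A circRNA on NC_035445.1 from 2850315 to 2853333 stood at 38200 ± 3358 on day 7 and was also listed at 0 in all late libraries. A circRNA on NC_035435.1 from 129518962 to 129556158, whose end coincides with an exon end of an assembled isoform of LOC110932224, was listed at 0 on day 7, at 1513 ± 496 on day 22 and at 142 ± 102 on day 37. A circRNA on NC_035443.1 from 22519684 to 22542214 rose from 47.3 to 721 ± 224 at day 22. From day 22 to day 37, a circRNA on NC_035443.1 from 139000695 to 139021809 fell from 578 ± 220 to 0. A circRNA on NC_035435.1 from 137950409 to 137956288, whose ends lie at exons assigned to the neighbours LOC110930261 and LOC110930260, fell from 367 ± 145 to 0. A circRNA on NC_035444.1 from 76408941 to 76438063 was listed at 0 on day 7, at 3863 ± 6690 on day 22, where 1 of the 3 libraries held all of its signal, and at 32370 ± 18760 on day 37. Its change from day 7 to day 37 had an adjusted p of 5.86e-03, and the call was lost with no filter.

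Of 645 circRNA tested, 17 rose and 324 fell at day 22, and 21 rose and 312 fell from day 7 to day 37. The filter asked for values above 0 in 3 libraries, and the day 7 libraries held the most circRNA above 0. The excess of falls thus partly repeats the difference in the number above 0 and is no separate evidence. From day 22 to day 37, 5 rose and 29 fell, and the risen share of 14.7% was 27.4% with median-of-ratios scaling. A fit of the 6 day 22 and day 37 libraries alone called 4 at this last step. Without day 37 replicate 3, 30 rose and 27 fell, so that leaving out this library turned the balance, and without both late libraries numbered 3, 21 rose and 31 fell. The risen count was 2 or 3 without day 22 replicate 2 or day 37 replicate 1 or 2. From day 7 to day 37, 44 rose and 285 fell without day 37 replicate 3. The calls of the risen circRNA on NC_035443.1 from 149031313 to 149033088, at 202 ± 154 on day 37 (SD, n = 3), and on NC_035441.1 from 175873817 to 175874185, at 159 ± 74.9, were lost when single libraries were left out.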

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

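The tests of the authors' scaling and of the summed circRNA signal were chosen after the results were seen, and the other tests of this part were set before their results.

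At 13102 single-exon loci assembled between annotated genes, signal was near 0 on day 7 and low but almost everywhere on the late days: 21.3% to 22.1% of the loci were above 0 in the day 7 libraries and 98.5% to 99.2% in the late libraries, with medians from 0.62 to 1.59 FPKM. A change of scaling cannot create signal from 0, and 67.9% of these loci were at 0 in all 3 day 7 libraries. Between day 22 and day 37, limma called 0.153% of the loci (6 risen, 14 fallen) once each library was divided by its median over them. At an unadjusted p under 0.05 were 6.89%. This cannot decide on transcription that changes locus by locus between these days. With the pseudocount and the threshold used, a locus at the median had to lose all its signal to be called as fallen. Genomic DNA in the late libraries and low transcription over the whole genome in older seeds cannot be told apart: loci overlapping on opposite strands differed by a median of at most 0.48 on the log2 scale, but random pairs differed by 0.63 to 0.72 and so also met the bound of 1 set for DNA. The rise of assembled lncRNA and of part of the mRNA features at day 22 may therefore stem from DNA or from RNA. The 16235 annotated genes at 0 in all day 7 libraries took medians of 0.2 to 0.44 FPKM later, with 87.0% to 88.7% of them above 0. They were picked by their day 7 values and could only stay or rise, so their rise is no separate support. The assembled loci may likewise have been found through reads of the late libraries.

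Fewer circRNA were above 0 in the late libraries than on day 7, with 433 ± 137 on day 22 and 476 ± 250 on day 37 against 1154 ± 72.2 (SD, n = 3 libraries per day). Junctions that span several genes do not account for it, since circRNA under 5 kb fell as well, from 972 ± 85.9 to 316 ± 117 and 401 ± 242, with a lower ratio of 2.43 between day 7 and a late day. The summed circRNA signal fell from 391000 ± 13070 to 43000 ± 30200 and 65370 ± 40740, and day 7 signal thinned by the fall of the mRNA predicted 2.0 to 7.21 times the observed sum in the 6 late libraries, so a dilution that lowers mRNA and circRNA alike was argued against as the whole cause of the lower signal. For the number of circRNA above 0, such a dilution and a loss of circRNA cannot be told apart, since the same thinning predicted 1.27 to 2.52 times the observed number, above the bound of 1.5 in 5 libraries and below it in 1. The thinning took 1 step of the signal as 1 read, and the smaller steps of the late libraries as greater depth. Since the depth is unknown, the predicted numbers rest on that assumption. Fewer circRNA in older seeds, which the days of the design would give, stays open as an untested hypothesis.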

How the results depend on the processing

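The alternatives said here to be added, and the splits of the libraries, were chosen after the results were seen. Of the values of named genes, 1268 kept direction and side of the threshold under the alternatives set in advance, 15 lost and 15 gained a call and 4 reversed; under the added ones the numbers were 338, 1, 9 and 2. LOC110932526 at day 22 reversed to 1.45 with quantile normalization and to 0.20 with the added scaling on 453 genes, and the gene with ID 110886340 to 1.36 and 0.10. LOC110877981 (1.15) and MXLOC_215740 (0.89) reversed at day 22 with quantile normalization. The cause was not tested for these, nor for the counts below, except where fewer features were tested.

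For mRNA, a filter at 5 FPKM, which tests fewer features, gave 10136 calls at day 22 and 13141 from day 7 to day 37. Quantile normalization gave 12423 at day 22, and the adjusted p alone 9673 from day 22 to day 37. Of the added ones, annotated genes alone gave 14060 at day 22, and a filter at 10 FPKM 6601, 3869 and 8457, each with fewer features tested. Leaving out features higher in replicate 3 gave 10584 and 15268 against day 7. That follows from its construction and tests nothing, as it picks features by their late values and removes 81.6% of the risen and 5.7% of the fallen features at day 22. With the adjusted p alone, 1662 mRNA features rose and fell, 1162 rose at both steps, 3988 fell at both and 87 fell and rose. These numbers were 1026, 446, 1025 and 244 with median-of-ratios scaling, 1311, 323, 3330 and 105 with a pseudocount of 0.1, 1855, 162, 1025 and 25 with the added scaling, and 1160, 241, 1865 and 193 without both late libraries numbered 3. Leaving out 1 library at a time, also added here, gave 824 to 1200, 68 to 258, 1574 to 3018 and 12 to 426. The 258 and the 426 were without day 37 replicate 3. The number that fell and rose was 18 without day 22 replicate 2, 19 without day 22 replicate 3 and 15 without day 37 replicate 1.

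For lncRNA, in the order day 22 against day 7, day 37 against day 22 and day 37 against day 7, a filter at 5 FPKM gave 4104, 468 and 4437 calls, median-of-ratios scaling 12621, 500 and 14775, trimmed mean scaling 11703, 226 and 11872, and quantile normalization 5808, 357 and 6625. The filter was applied after both scaling steps, which left 17127 and 14416 features to test. A pseudocount of 0.1 gave 1414 from day 22 to day 37. The adjusted p alone gave 32324 at day 22 and 1596 from day 22 to day 37. Of the added ones, the scaling on mRNA genes gave 104 from day 22 to day 37, leaving out features higher in replicate 3, by the same construction, gave 2525 and 4439 against day 7, annotated lncRNA alone 420, 281 and 890, and a filter at 10 FPKM 1743, 268 and 1905. The numbers that rose and fell, rose at both steps, fell at both, and fell and rose were 36, 21, 343 and 18 with median-of-ratios scaling, 203, 401, 188 and 10 with a pseudocount of 0.1, 272, 603, 253 and 17 with the adjusted p alone, and 58, 2, 1 and 0 with the added scaling. Leaving out features higher in replicate 3 left 23 that rose at both steps. Leaving out 1 library at a time gave 122 to 160, 62 to 224, 62 to 128 and 3 to 10. The 224 were without day 22 replicate 3, the 128 without day 37 replicate 1, which gave 144 that rose at both, and the 10 without day 37 replicate 3. The number that fell and rose was 7 without day 22 replicate 1 and 5 without day 7 replicate 1.

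For circRNA, asking for values above 0 in 5 libraries gave 149 and 138 calls against day 7, and median-of-ratios scaling 213 at day 22 and 62 from day 22 to day 37. A pseudocount 10 times as large gave 107, 8 and 108. From day 22 to day 37 the added scaling gave 55, and leaving out both late libraries numbered 3 gave 52. With the lower quartile of values above 0 as the minimum, 1153.7 circRNA were counted per day 7 library, 231.7 per day 22 library and 266.3 per day 37 library. The lowest values above 0 of the day 7 libraries were not under this minimum of 28, so it could lower only the late numbers.

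Leaving out 1 library at a time gave 17858 to 23783, 4726 to 7982 and 26460 to 29593 mRNA calls, 17333 to 26094, 601 to 1228 and 27321 to 30775 lncRNA calls, and 295 to 355, 25 to 57 and 309 to 355 circRNA calls. The 1228 (390 risen, 838 fallen) were without day 22 replicate 3 and the 57 (30 risen, 27 fallen) without day 37 replicate 3. Without day 37 replicate 3, 1321 mRNA rose and 5069 fell from day 22 to day 37, and without day 37 replicate 2, 185 rose. From day 22 to day 37, the call of LOC110895162 was gained without day 37 replicate 3 (log2 change 2.39), that of MXLOC_215740 without the same library (1.32) and that of the gene with ID 110886340 without day 37 replicate 1 (−2.34). With the replicate number as a block, 21788, 7114 and 28561 mRNA, 21401, 870 and 30149 lncRNA and 345, 31 and 332 circRNA were called. The block gained the call of LOC110895162, lost that of the circRNA on NC_035441.1 and changed no other call of a named gene. Day 7 libraries correlated with late libraries of equal number at −0.07 to 0.06 in all 3 tables, so there the block rests on a number alone. Between the late days, not every library correlated best with its own number.

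For each comparison of 2 days there are 10 splits of the 6 libraries, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave the highest count. In the order above, the real and the highest other count were 21867 and 0, 5967 and 0, and 28060 and 0 for mRNA, 21409 and 1, 854 and 315, and 30150 and 0 for lncRNA, and 343 and 1, 4 and 0, and 324 and 0 for circRNA. The limma tests of the other mRNA splits gave at most 17, 4445 and 8 features at an unadjusted p under 0.05, those of lncRNA from day 7 to day 37 at most 22, and those of circRNA at most 45 from day 22 to day 37 and 9 from day 7 to day 37. The 45, with day 22 replicate 1 and day 37 replicates 1 and 2 against the rest, stood against 46 for the real circRNA split, so unadjusted circRNA changes at this step do not set the days apart. The lncRNA split with 315 calls, which set day 22 replicates 1 and 2 with day 37 replicate 1 against the other 3 libraries, had 11743 at an unadjusted p under 0.05 against 3977 for the real split, which points to a structure of the late libraries beside the day. The 3 other splits of day 22 and day 37 that part all 3 pairs called 0 mRNA, at most 1 lncRNA and 0 circRNA, with at most 142, 443 and 1 at an unadjusted p under 0.05. Of 100 splits of the 9 libraries into 3 groups, 1 gave as many mRNA features called in any comparison as the real 30262 (highest other 27187), and 2 as many lncRNA as the real 30752 (highest other 30974), the real one included. Besides the real split, only 3 of those drawn for each table kept the day 7 libraries together. They gave up to 27187 mRNA and 30974 lncRNA features, against at most 18934 and 20666 where the day 7 libraries were parted. Few splits of 9 libraries can set day 7 apart, so chance is not excluded for that. Nor is it for parting day 22 from day 37, since the split with 30974 lncRNA features mixed these days. Count tests and tests of gene lists were not run, as the files hold no counts and no product names. The unknown depth leaves the precision of low values open.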

Other observations

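The thresholds that define the sets of this part, the test of neighbouring genes and the counts with libraries left out were chosen after the values were seen.

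Sets of features high on some days and low on the others were taken by thresholds, so their contrast between days follows from how they were picked. The days sampled cannot tell a sudden change from a gradual one. A set of 91 mRNA features held at least 100 FPKM in all day 7 libraries and less than 5 FPKM in all 6 late libraries, 81 of them annotated genes. Among the 81 is the gene with ID 110930822, which has no match in the gene table. Its means and SDs equal those of LOC110930790, also in the set, on each day, so this level may be counted more than once. The 91 features took 11.7% to 12.6% of the mRNA FPKM of the day 7 libraries and 0.0133% to 0.0421% of that of the late libraries. Conversely, 66 features held at least 50 FPKM in all late libraries and less than 5 FPKM on day 7, of which 36 were annotated. They took 3.8% to 12.7% of the late FPKM, and 34 of them were higher and 27 lower in replicate 3 than in replicate 1 on both late days. The set held 87 features without day 22 replicate 1, 77 without day 37 replicate 3 and 91 without both late libraries numbered 3. Only 14 features were at 50 FPKM or more in all day 22 libraries and below 5 FPKM in the other 6 libraries, and 0 were so on day 37 alone. All 14 were lower in replicate 3 on both late days, and without day 22 replicate 3 the set held 23. Without day 37 replicate 3, 1 feature was restricted to day 37, LOC110889963 at 84.55, 66.25 and 21.47 FPKM, so the 0 rested on that library. Among the 14 were LOC110927702, LOC110879816, MXLOC_041393 (238 FPKM on day 22), LOC110929248 (134 FPKM) and LOC110930689 (131 FPKM). In the gene order of HanXRQr2.0-SUNRISE, 6 of the 13 annotated genes among them lie on chromosome 3, including LOC110927702, LOC110929248 and LOC110930689. MXLOC_041393 has no place in that order. The share of all genes on this chromosome was not computed and it was picked after the positions were seen, so a cluster was not tested.

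The 3 circRNA with the most signal took 27.2% to 31.4% of the circRNA signal in the day 7 libraries, 22.9% to 28.3% on day 22, and 50.1%, 57.3% and 62.9% on day 37. Inside the interval of the day 7 circRNA on NC_035433.1 from 75074236 to 75089399 lies an assembled locus antisense to LOC110937061. That gene is one of the 91 features of day 7, at 1999 FPKM, and so is its neighbour LOC110937069, at 1469 FPKM.

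Several of the 91 day 7 features were neighbours in the gene order. Of the 80 with a place in it, 15 had another within 3 gene positions, against a median of 2 and a highest value of 11 in 10000 random draws from the 664 genes with at least 100 FPKM on day 7 (permutation p = 0.0001, the smallest they can give). LOC110897314, LOC110897316 and LOC110897318 on chromosome 13 carried 2289, 4148 and 5320 FPKM on day 7, and LOC110865032 and LOC110865031 on chromosome 6 carried 8105 and 1617 FPKM. A candidate explanation is a set of gene clusters used early in seed development, and another is near-identical copies among which reads were shared equally. For the latter, the day 7 levels of 9 neighbour pairs differed by a median of 0.44 on the log2 scale (range 0.246 to 2.33), against 1.23 for all pairs of these genes. No pair was equal, and near levels could also come from clusters used together, so this does not separate the 2 explanations. LOC110930790 and the gene with ID 110930822 are not among the 9 pairs and had equal means and SDs on each day.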
